A study of Homo sapiens with 14 samples.

How the data were processed

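The study measured gene expression by RNA sequencing in neural ectoderm derived from H9 cells, an established human embryonic stem cell line. Total RNA had been extracted with Trizol and sequenced on an Illumina platform, per the labels' protocols. The labels give 14 samples in 7 groups of 2: a solvent control with 0.1% DMSO, 5 single compounds and a mixture of the 5. One BDE-47 sample is not analysed here, so 13 libraries entered every fit and the BDE-47 group rested on 1 library, which was assumed to vary like the other groups. The labels do not state whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not state whether the mixture held 1 µM of each compound or 1 µM in total.

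The authors deposited 1 table per library with gene-level FPKM values at 2 decimals. Per the submitters' processing notes, HISAT, Bowtie2, RSEM and the hg38 build were used, with no versions and no order of steps given in the sources used here. The planned test assumed counts. The files held FPKM, so the fallback written beside it for such values was used: limma with an intensity trend on log2(FPKM + 1). Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. Each table listed 19314 genes, of which 1248 were blank in every file, 18066 had values and 25 were at 0 in every library. In 28 cases a spreadsheet had turned the gene symbol into a date, and the symbol was restored from the gene identifier. No mitochondrially encoded gene was listed.

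Depth is not given by FPKM values. Ratios of low values to those of the first control library were taken, and only ratios between 0.75 and 1.33 were kept. Their median was 1.0 for all other 12 libraries, with 13 to 20 genes per library. That window drops the ratios a very different depth would give, and values are rounded to 2 decimals. The look therefore does not settle depth. FPKM summed to between 412457 and 433085 per library, and 1385 to 1538 genes per library were at 0. The correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.9969 to 0.9982 between libraries of 1 group and 0.9951 to 0.9981 between libraries of different groups, so no pair stood out as 1 library given under 2 names.

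Genes with a mean FPKM of at least 1 were tested, 12488 in all. The model had 1 coefficient per group, no term for the replicate number and 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg (BH) method with a threshold of 0.05. Of the contrasts, 6 set each treatment against control, and 5 set compounds against each other or the mixture against the equally weighted mean of the 5 single compounds. Before the data were examined, 39 gene lists, the tests, the other settings to be tried and the rule for naming genes were fixed. Of the lists, 36 had at least 5 tested members. Counts of higher or lower members below are of tested members only, which were 7 of 18 for hedgehog signalling, 6 of 12 for AHR targets and 7 of 32 for histones. The 36 lists were tested with limma's camera at a preset correlation of 0.01, with BH adjustment over all 396 list tests together. The same lists were tested by camera with an estimated correlation, by fry, and, as an addition made after the data were seen, by limma on each library's mean over the list. Some counts below give members that passed limma with BH adjustment over the list alone. Those lists had already been called on the same values, so such counts describe a list and do not support its single members.

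Genes were named by rule. Against control, it took among genes past an adjusted p of 0.05 the 8 largest rises and 8 largest falls with all treated libraries on one side of both controls. Where fewer than 5 genes passed, it took the 5 smallest unadjusted p-values in each direction, as values only. It added up to 4 members of each list past its threshold, up to 5 genes in each direction for contrasts between compounds, and 21 background markers. Read-through transcripts and genes with near-identical copies share reads with their neighbours or copies and are uncertain. Some genes that the rule or the first principal component would name are not reported here.

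The fit was tested on simulated data modelled on TBBPS against control with 12488 genes, 200 of them changed in each of 10 runs. It called 75% of genes changed by a log2 fold of 0.5, 96.6% of those changed by 1 and 99.6% of those changed by 2, and 0.0594% of unchanged genes. Genes were drawn independently, with no structure shared between libraries, and the shares depend on the number and size of the changes put in. They are therefore not the power in the real libraries, where an absence of calls does not exclude changes of 0.5. Alternatives planned in advance were a fit of only the groups compared, the replicate number as a block, leaving out the BDE-47 library, a threshold of 0.01, a pseudocount of 0.1, no filter on low values and leaving out each library in turn. Alternatives added after the data were seen were quantile normalization, removal of each library's trend with GC content and transcript length (12308 of 12488 genes had both values), and leaving out the 5 treated libraries numbered 1 together. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.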

Results

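RNA from neural ectoderm, the embryonic layer that gives rise to the nervous system, was compared between H9-derived cells treated with halogenated flame retardants and cells given 0.1% DMSO. The compounds were BDE-47, a tetrabrominated diphenyl ether; BDE-209, the fully brominated diphenyl ether; tetrabromobisphenol A (TBBPA); tetrabromobisphenol S (TBBPS), which carries a sulfonyl bridge where TBBPA has isopropylidene; and TCBPA, the analogue of TBBPA with chlorine in place of bromine. The dose was 1 µM. Each group had 2 libraries except BDE-47, which had 1. The question was how these compounds affect early human neural development, alone and together. Levels below are mean FPKM ± SD over 2 libraries, and changes are log2 fold changes ± SE.

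The cells carried a neural ectoderm profile in every group. SOX2, a neural progenitor factor, stood at 346 ± 3.52 FPKM in controls and between 352 and 385 in the treated group means. OTX2, a forebrain and midbrain regulator, was at 137 ± 2.99 FPKM in controls. PAX6, which marks human neuroectoderm, was at 123 ± 1.90 in controls and 95.4 ± 7.87 with TCBPA. The pluripotency factors POU5F1 and NANOG were low, at 2.15 ± 0.148 and 1.08 ± 0.0212 FPKM in controls. No HOX gene of the posterior list reached the tested range, with 0 of 30 members tested.

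Libraries differed along an axis that did not follow the groups alone. The first principal component held 33.7% of the variance. Controls lay at -7.05 and -9.61 and the BDE-47 library at -12.07. The libraries numbered 1 of BDE-209, TBBPA, TBBPS, TCBPA and the mixture lay at 3.30, 8.93, 10.71, 8.72 and 9.04, and those numbered 2 at -5.10, -5.63, -2.15, 2.46 and -1.55.

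**Figure D1:**
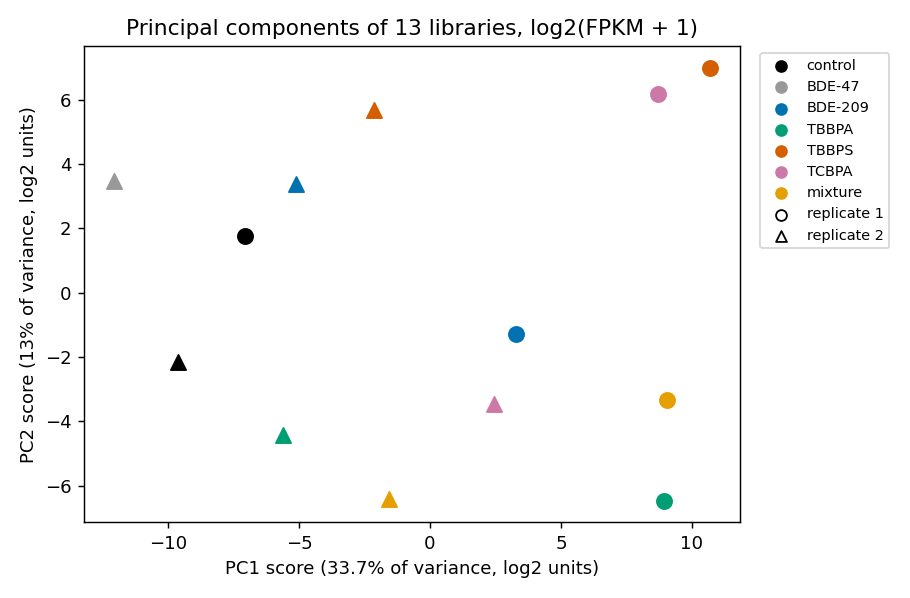
Principal components of log2(FPKM + 1) for the 13 libraries, with component 1 (33.7% of variance) on the horizontal axis and component 2 (13%) on the vertical axis, each point a library. The 5 treated libraries numbered 1 other than BDE-47 lie between 3.30 and 10.71 on component 1, and the controls at -7.05 and -9.61.

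Gene groups passed their test more often than single genes in a model with no term for the replicate number. There, limma with BH adjustment found that 1 of 12488 genes changed with TCBPA and 0 with each of the other 5 treatments. With the replicate number as a block, 3 passed with BDE-209, 1 with TBBPA, 273 with TBBPS, 452 with TCBPA and 115 with the mixture. The labels do not say that a number marks a shared culture, batch or day. Results for single genes below are from the model without that term unless stated. At an unadjusted p under 0.05 there were 523 genes with BDE-47, 735 with BDE-209, 1062 with TBBPA, 1473 with TBBPS, 1966 with TCBPA and 1222 with the mixture, where chance gives 624. Of 396 list tests, camera with its preset correlation called 115. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.443, and fry and limma on list means each called 0, with lowest adjusted p-values of 0.0826 and 0.0823. Every list result below is a call of camera at the preset correlation, and words such as rose and fell refer to it.

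TCBPA gave the most genes at an unadjusted p under 0.05 of the 6 treatments. SFPQ, a splicing and paraspeckle protein gene, fell from 113 ± 8.67 FPKM in controls to 77.3 ± 3.30. Genes induced by p53 and feedback genes of the FGF and ERK pathway rose as groups, and mitosis genes and hedgehog pathway genes fell as groups. Genes of neurogenesis, placode and surface ectoderm, oxidative defence and the interferon response also rose.

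SFPQ (Entrez gene 6421, chromosome 1, 35176380 to 35193145 in GRCh38) changed by -0.53 ± 0.06 with a limma BH-adjusted p of 0.0288, and both TCBPA libraries lay below both controls. Other genes with small p-values did not pass and are given as values. PLK2, a kinase induced by stress, was at 58.4 ± 0.891 FPKM against 46.3 ± 0.566 in controls, and GDF15, a secreted stress cytokine gene, differed by 0.52 ± 0.08. PLA2G16, a phospholipase, differed by 0.69 ± 0.10, the syntaxin gene STX3 by 0.35 ± 0.05 and the lactate transporter gene SLC16A1 by 0.26 ± 0.04. On the lower side were the receptor gene S1PR1 at -0.52 ± 0.07, the RNA polymerase II subunit gene POLR2I at -0.53 ± 0.08, the coactivator gene NCOA5 at -0.38 ± 0.05 and the spindle gene ASPM at -0.34 ± 0.06. The SFPQ call was lost without control 2 (adjusted p = 0.442), TCBPA 1 (0.287) or TCBPA 2 (0.0562), without the filter on low values (0.0839), with quantile normalization (0.0591) and with the 5 treated libraries numbered 1 left out (0.111). A fit of only the TCBPA and control libraries called 158 genes, SFPQ among them. SFPQ also passed with the replicate number as a block, with a pseudocount of 0.1, with GC and length trends removed and with the BDE-47 library left out.

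Among p53 targets, 21 of 24 members were higher with TCBPA and the median difference was 0.14 (camera, BH-adjusted p = 3.7e-08; adjusted p = 0.447 with an estimated correlation). No member passed over all genes tested. Adjusted over the list alone, which had already been called on the same values, 8 passed, among them GDF15, RRM2B, PLK3 and CDKN1A. RRM2B, a ribonucleotide reductase subunit gene used in DNA repair, was at 31.7 ± 2.17 FPKM against 24.2 ± 1.44. CDKN1A, which encodes the cell cycle inhibitor p21, was at 143 ± 28.2 against 99.9 ± 5.18, and the kinase gene PLK3 differed by 0.37 ± 0.07. Mitosis genes fell with a median of -0.17 and 24 of 24 lower (adjusted p = 3.0e-10; 0.443 with an estimated correlation), and 12 passed when adjusted over the list alone. The kinetochore gene CENPF was at 41.8 ± 1.44 FPKM against 52.5 ± 2.33 and the proliferation marker MKI67 at 32.6 ± 3.51 against 39.8 ± 1.73. DNA replication genes fell by 0.10 at the median, 20 of 25 lower (adjusted p = 0.00365; 0.518 with an estimated correlation), a call lost without TCBPA 1.

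FGF and ERK feedback genes rose with TCBPA by a median of 0.27, 17 of 19 higher, 16 of them with both TCBPA libraries above both controls, where chance puts 16.7% of genes and 25.2% of all tested genes lay so (adjusted p = 2.7e-06; 0.464 with an estimated correlation). The ETS factor gene ETV4 was at 11.1 ± 1.51 FPKM against 7.03 ± 0.523 and the ERK phosphatase gene DUSP4 at 27.7 ± 0.0354 against 19.7 ± 0.594. Of the 18 hedgehog list members 7 were tested. All 7 were lower, with a median of -0.15 (adjusted p = 1.8e-04; 0.443 with an estimated correlation), and 6 passed when adjusted over the list alone. PTCH1, the hedgehog receptor and a target of the pathway, was at 5.45 ± 0.523 FPKM against 8.04 ± 0.156. Placode and surface ectoderm genes had a median of 0.25, 17 of 18 higher (adjusted p = 3.7e-05; 0.51 with an estimated correlation), with the tight junction gene CLDN7 at 16.2 ± 1.39 against 11.1 ± 0.615. Neurogenesis genes had a median of 0.21, 17 of 24 higher (adjusted p = 0.00167; 0.654 with an estimated correlation), with ELAVL2, a neuronal RNA-binding protein gene, at 4.29 ± 0.368 against 2.73 ± 0.0283.

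Stress and metabolic lists were also higher with TCBPA. NRF2 targets of oxidative defence had a median of 0.15, 18 of 22 higher (adjusted p = 0.00151; 0.443 with an estimated correlation). TXNRD1, thioredoxin reductase, was at 60.5 ± 0.573 FPKM against 54.4 ± 0.184, and HMOX1, haem oxygenase, at 2.44 ± 0.368 against 1.74 ± 0.106. The interferon list had a median of 0.06, 12 of 16 higher (0.0196; 0.443 with an estimated correlation), with the ubiquitin-like protein gene ISG15 at 14.5 ± 1.03 against 11.6 ± 1.34 and B2M, the MHC class I light chain gene, at 124 ± 4.75 against 100 ± 2.78. Immediate early genes (0.16, 12 of 16 higher), AHR targets (0.16, 6 of 6), PPAR targets (0.14, 10 of 12), cholesterol synthesis (0.07, 17 of 24), heat shock (0.09, 14 of 16), ER chaperones (0.06, 18 of 20) and nuclear oxidative phosphorylation (0.05, 24 of 34) passed with adjusted p-values from 0.00149 to 0.0191, and 0.443 to 0.589 with an estimated correlation. Each of these 7 calls was lost without TCBPA 1 or without TCBPA 2. DUSP1, an immediate early phosphatase gene, was at 9.46 ± 0.438 against 7.02 ± 0.219, CYP1A1, the classic AHR-induced gene, at 5.07 ± 0.467 against 3.86 ± 0.0707, and ANGPTL4, a PPAR target, at 8.16 ± 0.134 against 5.46 ± 0.163.

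With TBBPS, hedgehog pathway genes and genes of the BMP and TGF-beta target list fell. NRF2 targets, heat shock genes, immediate early genes, FGF and ERK feedback genes and nuclear oxidative phosphorylation genes rose. No single gene passed limma with BH adjustment (0 of 12488), with 1473 at an unadjusted p under 0.05 and a smallest adjusted p of 0.228.

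All 7 tested hedgehog genes were lower with TBBPS, with a median of -0.15 (camera, BH-adjusted p = 1.9e-04; 0.443 with an estimated correlation), and PTCH1, GAS1, BOC, GLI3 and SMO passed when adjusted over the list alone. BOC, a hedgehog co-receptor gene, was at 28.6 ± 3.85 FPKM against 35.5 ± 0.693. BMP and TGF-beta targets had a median of -0.13 with 15 of 19 lower (0.00114; 0.443 with an estimated correlation). The ligand genes BMP7 and BMP4 stood at 27.4 ± 3.69 against 37.4 ± 4.21 and at 34.2 ± 0.919 against 41.4 ± 0.693. Since the list named for targets also holds ligand and antagonist genes, it does not measure the output of the pathways alone. NRF2 targets had a median of 0.11 with 20 of 22 higher (2.6e-04; 0.443 with an estimated correlation), with TXNRD1 at 62.7 ± 1.75 against 54.4 ± 0.184 and TXN, thioredoxin, at 134 ± 4.37 against 116 ± 1.51. Heat shock genes had a median of 0.13 with 16 of 16 higher (5.7e-05; 0.443 with an estimated correlation), with the chaperone gene HSPA8 at 398 ± 7.99 against 350 ± 7.46. Immediate early genes had a median of 0.17 with 15 of 16 higher (6.2e-04; 0.464 with an estimated correlation), with JUNB at 4.97 ± 0.113 against 3.74 ± 0.361.

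With TBBPS, FGF and ERK feedback genes had a median of 0.15, 17 of 19 higher (camera, BH-adjusted p = 8.6e-05; 0.486 with an estimated correlation). SPRY4, a Sprouty inhibitor of the pathway, was at 4.22 ± 1.24 FPKM against 2.04 ± 0.00707. Neurogenesis genes had a median of 0.19, 17 of 24 higher (0.00129; 0.651 with an estimated correlation), and TAGLN3, a neuronal cytoskeletal gene, stood at 29.1 ± 0.290 against 21.6 ± 0.262. Placode and surface ectoderm genes had a median of 0.12, 16 of 18 higher (0.0093; 0.647 with an estimated correlation). Without TBBPS 1, which lay at 10.71 on the first component, the neurogenesis and placode calls were lost with medians of 0.09 and 0.04, the DNA replication call below was lost and the NRF2 median was 0.06. Without TBBPS 2 the FGF and ERK median was 0.24 and the BMP and TGF-beta median -0.22. Nuclear oxidative phosphorylation genes had a median of 0.07, 29 of 34 higher (3.9e-05; 0.464 with an estimated correlation). DNA replication genes had a median of -0.09, 19 of 25 lower (0.00116; 0.5 with an estimated correlation), with the helicase gene MCM5 at 29.6 ± 1.65 against 35.9 in controls. Mitosis genes (0.06, 23 of 24 higher), AHR targets (0.11, 6 of 6), axon guidance (-0.06, 18 of 32 lower), histones (0.21, 4 of 7) and cytosolic ribosomal proteins (0.05, 60 of 64) passed with adjusted p-values from 1.8e-04 to 0.0487, and 0.443 to 0.684 with an estimated correlation. The ribosomal call was lost with quantile normalization (median 0.01), and the other 4 were lost without TBBPS 2. Among AHR targets, CYP1A1 was at 3.86 ± 0.0778 FPKM against 3.86 ± 0.0707 with TBBPS and CYP1B1 at 4.91 ± 0.283 against 4.88 ± 0.488.

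Genes with the smallest p-values with TBBPS did not pass. S1PR1 was at 10.6 ± 0.834 FPKM against 14.9 ± 0.0849, the chromatin reader gene ZMYND8 at 18.5 ± 0.573 against 23.9 ± 1.07, and the kinase gene UCKL1 at 4.25 ± 0.0990 against 6.20 ± 0.0212. STARD4, a sterol transport gene, differed by 0.37 ± 0.06, the ciliary gene BBS7 by 0.36 ± 0.06, the histone chaperone gene NAP1L2 by 0.36 ± 0.06 and the kinase gene PIM3 by 0.31 ± 0.06. SOX1, an early neural plate marker, differed by -0.31 ± 0.08, and TIPARP, an AHR target, was at 4.58 ± 0.177 against 3.84 ± 0.0354.

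TBBPA raised genes of cholesterol synthesis and lowered genes of mitosis as groups. Placode and surface ectoderm genes, neurogenesis genes, FGF and ERK feedback genes, immediate early genes and interferon response genes also rose. Hedgehog and hypoxia or glycolysis genes fell. By limma with BH adjustment 0 genes passed, with 1062 at an unadjusted p under 0.05 and a smallest adjusted p of 0.517.

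In the cholesterol list, 23 of 24 members were higher with TBBPA and the median was 0.13 (camera, BH-adjusted p = 5.4e-08; 0.443 with an estimated correlation). FDFT1 and INSIG1 were among the members that passed when adjusted over the list alone. INSIG1, a sterol sensor target, was at 16.9 ± 0.0495 FPKM against 13.5 ± 0.962, and squalene synthase FDFT1 at 119 ± 5.73 against 102 ± 0.587. All 24 mitosis genes were lower, with a median of -0.14 and 22 with both TBBPA libraries below both controls, as were 19.4% of all tested genes (1.4e-12; 0.443 with an estimated correlation). The kinetochore motor gene CENPE was at 15.6 ± 1.30 against 18.5 ± 0.177 and the topoisomerase gene TOP2A at 138 ± 17.7 against 162 ± 4.16. Without TBBPA 1 the mitosis median was -0.09.

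Placode and surface ectoderm genes had a median of 0.31 with TBBPA, 16 of 18 higher (camera, BH-adjusted p = 6.2e-07; 0.464 with an estimated correlation), and KRT7, KRT18, KRT8 and CLDN7 passed when adjusted over the list alone. KRT8 and KRT18, keratins of simple epithelia, stood at 707 ± 36.7 FPKM against 582 ± 11.7 and at 488 ± 21.5 against 391 ± 7.95. Neurogenesis genes had a median of 0.25, 22 of 24 higher (8.2e-07; 0.524 with an estimated correlation), with INSM1, a factor of newborn neurons, at 5.67 ± 1.39 against 3.46 ± 0.587. FGF and ERK feedback genes had a median of 0.19, 17 of 19 higher (1.4e-05; 0.464 with an estimated correlation), with the Sprouty gene SPRY2 at 0.40 ± 0.13. Without TBBPA 1, which lay at 8.93 on the first component, these 3 medians were 0.15, 0.15 and 0.08, and without TBBPA 2 the neurogenesis median was 0.42 and the FGF and ERK median 0.29. Immediate early genes had a median of 0.15, 14 of 16 higher (8.7e-05; 0.443 with an estimated correlation), and interferon genes of 0.09, 12 of 16 higher (0.0188; 0.443 with an estimated correlation), with the membrane protein gene IFITM1 at 217 ± 1.38 against 170 ± 2.40. Hedgehog genes (-0.08, 7 of 7 lower) and hypoxia and glycolysis genes (-0.09, 21 of 29 lower) passed at 0.00804 and 0.00483, and 0.443 and 0.475 with an estimated correlation, calls lost without TBBPA 2 and without control 1. Lactate dehydrogenase LDHA was at 125 ± 1.14 against 163 ± 21.3. The oestrogen axis (0.10), histones (0.21) and cytosolic ribosomal proteins (0.06) passed at 0.034, 0.0487 and 0.00114, and 0.443, 0.443 and 0.738 with an estimated correlation. The first was lost without any 1 of the TBBPA or control libraries, and the others with quantile normalization.

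Among single genes with TBBPA, given as values, CARD8, an inflammasome regulator, was at 9.64 ± 0.304 FPKM against 12.7 ± 0.177, and the condensin gene NCAPG and the mitotic kinesin gene KIF2C differed by -0.23 ± 0.05 and -0.26 ± 0.06. On the higher side were LEMD1 at 0.36 ± 0.06, FNDC10 at 0.47 ± 0.09 and UEVLD at 0.35 ± 0.07. DIO3, the deiodinase that inactivates thyroid hormone, was at 3.91 ± 1.82 with TBBPA against 1.81 ± 0.332 in controls. The TBBPA libraries numbered 1 and 2 stood at 5.20 and 2.62. DIO3 was also at 5.02 ± 1.03 with TCBPA, 4.15 ± 0.332 with the mixture, 2.86 ± 0.643 with BDE-209, 2.57 ± 1.26 with TBBPS and 1.37 with BDE-47, so a higher value was not particular to TBBPA.

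The mixture raised FGF and ERK feedback genes and neurogenesis genes and lowered mitosis genes as groups. In the FGF and ERK list 19 of 19 members were higher, with a median of 0.24 (camera, BH-adjusted p = 3.9e-10; 0.443 with an estimated correlation), and 9 passed when adjusted over the list alone. ETV4 differed by 0.69 ± 0.16, DUSP4 was at 28.9 ± 1.58 FPKM against 19.7 ± 0.594 and the FGF receptor antagonist gene IL17RD at 29.7 ± 1.80 against 20.2 ± 0.106. Limma with BH adjustment called 0 single genes, with 1222 at an unadjusted p under 0.05 and a smallest adjusted p of 0.385.

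Neurogenesis genes had a median of 0.32 with the mixture, 23 of 24 higher (camera, BH-adjusted p = 9.3e-08; 0.505 with an estimated correlation). The proneural gene NEUROD1 differed by 0.57 ± 0.20, and RBFOX3, which encodes the neuronal antigen NeuN, was at 1.60 ± 0.0354 FPKM against 1.01 ± 0.0424. Without mixture 1, which lay at 9.04 on the first component, this median was 0.21. Mitosis genes had a median of -0.14, 23 of 24 lower (1.7e-11; 0.443 with an estimated correlation), with cyclin gene CCNB2 at 88.6 ± 2.74 against 106 ± 4.79. Placode genes (0.21, 17 of 18 higher) passed at 2.0e-04, AHR targets (0.16, 5 of 6) at 0.0189 and immediate early genes (0.11, 12 of 16) at 0.0168, with 0.524, 0.443 and 0.524 with an estimated correlation. The placode and AHR calls were lost without mixture 1 and the immediate early call without mixture 2. Cytosolic ribosomal protein genes (-0.09, 56 of 64 lower) and nuclear oxidative phosphorylation genes (-0.05, 25 of 34 lower) fell with adjusted p-values of 3.4e-09 and 0.0088, and 0.539 and 0.552 with an estimated correlation. Both calls were lost without mixture 2 and with quantile normalization, where the medians were each -0.02.

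Single genes of the mixture comparison are given as values. IFI16, an interferon-inducible DNA sensor gene, differed by 0.65 ± 0.11, the actin regulator gene CORO2B was at 4.97 ± 0.410 FPKM against 3.09 ± 0.339, and NFE2L2, which encodes NRF2, at 27.2 ± 1.07 against 22.4 ± 0.0778. S1PR1 was at 11.3 ± 0.636 against 14.9 ± 0.0849 and CNPY2 at 43.5 ± 0.707 against 50.6 ± 0.615. The read-through locus TGIF2-C20orf24 was listed at 0 in both mixture libraries and is uncertain.

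**Figure D2:**
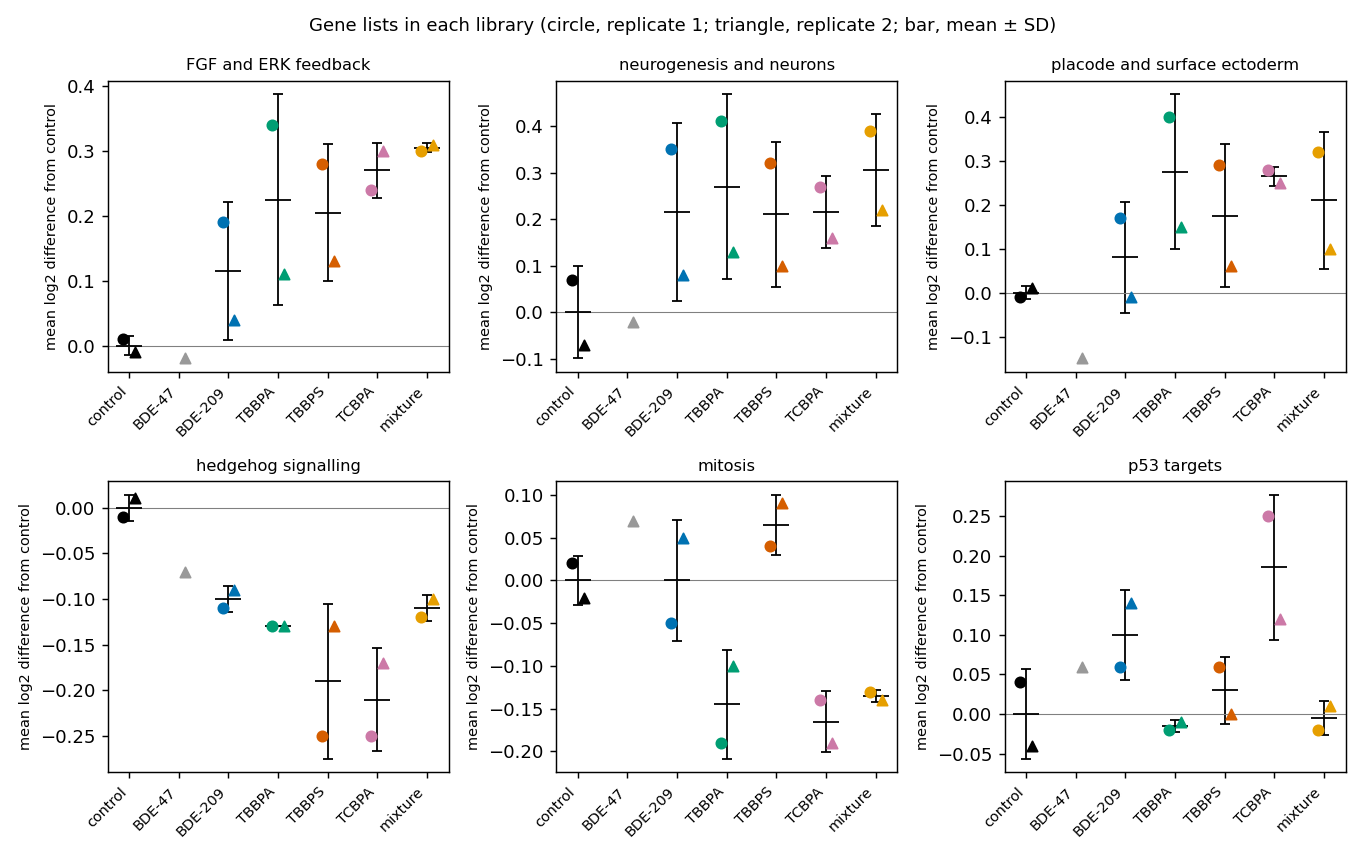
Mean log2 difference from control over the members of 6 gene lists (vertical axes) in each library by group (horizontal axes), with circles for libraries numbered 1, triangles for those numbered 2 and bars for mean ± SD. The mitosis list had a mean difference of -0.23 between TCBPA and TBBPS, and 0.20 between TBBPS and TBBPA.

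BDE-209 shifted several lists by small amounts, none of them independently of single libraries. Neurogenesis genes, p53 targets, amino acid stress genes of the ATF4 pathway and DNA replication genes were higher as groups, and BMP and TGF-beta targets were lower. Single genes past limma with BH adjustment numbered 0, with 735 at an unadjusted p under 0.05 and a smallest adjusted p of 0.844. Neurogenesis genes had a median of 0.21, 21 of 24 higher (camera, BH-adjusted p = 4.3e-05; 0.552 with an estimated correlation), with ELAVL2 at 4.23 ± 1.12 FPKM against 2.73 ± 0.0283. Without BDE-209 1 the call was lost and the median was 0.07. p53 targets had a median of 0.10, 20 of 24 higher (7.6e-05; 0.518 with an estimated correlation), with PLK3 at 4.98 ± 0.0495 against 4.10 ± 0.134. ATF4 genes had a median of 0.12, 22 of 26 higher (4.5e-04; 0.603 with an estimated correlation), with the folate enzyme gene MTHFD2 at 56.4 ± 5.93 against 46.6 ± 1.53. Without BDE-209 2 the ATF4 median was 0.00 and the list's direction turned. DNA replication genes had a median of 0.07, 22 of 25 higher (3.0e-04; 0.471 with an estimated correlation). BMP and TGF-beta targets had a median of -0.15, 12 of 19 lower (0.0101; 0.475 with an estimated correlation), with BMP2 at 7.40 ± 0.0354 against 9.78 ± 1.14. ER chaperones (0.06), FGF and ERK feedback (0.07), hedgehog (-0.07), hypoxia and glycolysis (-0.08) and nuclear oxidative phosphorylation (0.05) passed with adjusted p-values from 0.00265 to 0.0314, and 0.443 to 0.654 with an estimated correlation. Each of the 10 calls was lost without at least 1 BDE-209 or control library.

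Genes with the smallest p-values with BDE-209 did not pass. FOXJ1, the master regulator of motile cilia, was at 4.34 ± 0.0919 FPKM against 6.53 ± 0.170, and LYPD1 at 5.04 ± 0.813 against 7.54 ± 0.700, and the repressor gene BCL6 differed by -0.34 ± 0.07. Adenosine deaminase ADA was at 10.8 ± 0.849 against 7.52 ± 0.0778, the ATP synthase gene ATP5G1 at 59.9 ± 0.721 against 51.0 ± 0.417 and GPT2, a mitochondrial transaminase gene, differed by 0.27 ± 0.06.

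BDE-47 was represented by 1 library, whose profile lay beside the controls. Cytosolic ribosomal protein genes, nuclear oxidative phosphorylation genes, mitosis genes, p53 targets and anterior neural ectoderm genes were higher as groups, by medians of 0.08, 0.07, 0.07, 0.02 and 0.05. By limma with BH adjustment 0 genes passed, with 523 at an unadjusted p under 0.05 and a smallest adjusted p of 0.978. The spread in these tests came from the other groups, so they do not separate an effect of BDE-47 from the deviation of this 1 library. Camera's BH-adjusted p-values were 5.8e-10, 5.7e-05, 2.2e-04, 0.0264 and 0.0252, and 0.464 to 0.687 with an estimated correlation. Ribosomal RPS19 was at 1870 FPKM against 1640 ± 10.3 and the complex I gene NDUFB3 at 77.6 against 61.6 ± 2.38, and of the anterior list FABP7, a radial glia fatty acid binding protein gene, was at 274 against 236 ± 2.43. POU5F1 stood at 1.25 against 2.15 ± 0.148 and SOX4 at 56.8 against 66.1 ± 1.34. With quantile normalization 4 of the 5 calls were lost, the mitosis call being the exception, and the ribosomal median was 0.01. With GC and length trends removed the ribosomal median was 0.03 and the oxidative phosphorylation and p53 calls were lost.

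Comparing TBBPS with TBBPA, which differ in the bridge between the rings, mitosis genes were higher and BMP and TGF-beta targets lower with TBBPS. All 24 mitosis genes were higher, with a median of 0.21 (camera, BH-adjusted p = 5.9e-18, and 0.443 with an estimated correlation). Adjusted over the list alone, 18 passed. The mean difference by limma on list means was 0.20 (95% interval 0.10 to 0.31, unadjusted). After BH adjustment that test called 0 lists in this comparison, with a lowest adjusted p of 0.0823. CENPE was at 20.9 ± 0.212 FPKM with TBBPS and 15.6 ± 1.30 with TBBPA, and the spindle checkpoint gene BUB1 at 56.1 ± 3.09 and 46.2 ± 2.52. BMP and TGF-beta targets had a median of -0.29, 18 of 19 lower, and a mean difference of -0.28 (-0.42 to -0.15; adjusted p = 1.3e-06; 0.443 with an estimated correlation). BMP4 was at 34.2 ± 0.919 and 46.8 ± 1.56, and the BMP antagonist gene GREM1 at 1.06 ± 0.233 and 2.14 ± 0.325. Across genes, which are not independent replicates, log2 differences in this comparison correlated with GC content (rho = -0.38), more strongly than in any other comparison. With GC and length trends removed the mitosis median was 0.19. The BMP and TGF-beta median after that removal is not given here, so how much of it goes with GC content stays open. Limma with BH adjustment called 0 single genes, with 1561 at an unadjusted p under 0.05 and a smallest adjusted p of 0.188.

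Further lists separated TBBPS from TBBPA. Mesenchyme and extracellular matrix genes were lower (-0.12, 19 of 23; camera, BH-adjusted p = 6.1e-04; 0.443 with an estimated correlation), with the actin-binding gene TAGLN at 126 ± 13.4 FPKM and 184 ± 7.11, and the list median was -0.07 with GC and length trends removed. Heat shock genes were higher (0.10, 15 of 16; 1.1e-04; 0.443 with an estimated correlation), with HSP90AA1 at 534 ± 13.5 and 450 ± 41.5. WNT genes (-0.14), cholesterol synthesis (-0.10), ATF4 genes (-0.11), axon guidance (-0.12), DNA replication (-0.09) and the oestrogen axis (-0.11) were lower, and hypoxia and glycolysis (0.06), NRF2 targets (0.05) and nuclear oxidative phosphorylation (0.05) higher, with adjusted p-values from 0.00201 to 0.0387, and 0.443 to 0.684 with an estimated correlation. Each of these 9 calls was lost without 1 of the TBBPA or TBBPS libraries. For these lists and heat shock, medians with GC and length trends removed are not given here. LEF1, a WNT effector gene, was at 6.26 ± 0.332 and 7.50 ± 0.361. FGF and ERK feedback genes showed no detected difference, with a mean of -0.02 (-0.19 to 0.15), nor did hedgehog genes, with -0.06 (-0.16 to 0.04), or neurogenesis genes, with -0.06 (-0.32 to 0.20).

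TCBPA and TBBPA, which differ in the halogen, differed in p53 targets. In that list 22 of 24 members were higher with TCBPA, with a median of 0.18 (camera, BH-adjusted p = 2.3e-13; 0.443 with an estimated correlation). Adjusted over the list alone, 9 passed. The mean difference by limma on list means was 0.20 (95% interval 0.08 to 0.31, unadjusted). After BH adjustment that test called 0 lists between TCBPA and TBBPA, with a lowest adjusted p of 0.0898. RRM2B was at 31.7 ± 2.17 FPKM with TCBPA and 22.7 ± 0.177 with TBBPA, ZMAT3, a p53-induced RNA-binding protein gene, at 19.0 ± 1.53 and 14.2 ± 0.141, and GDF15 differed by 0.50 ± 0.08. Without TCBPA 1 the median was 0.11. DNA replication (-0.05), anterior neural ectoderm (-0.10), heat shock (0.08), ER chaperones (0.06) and NRF2 targets (0.06) passed with adjusted p-values from 0.00483 to 0.0376, and 0.443 to 0.552 with an estimated correlation, each call lost without 1 of the 4 libraries. Of the anterior list, FABP7 was at 192 ± 10.7 and 239 ± 19.1, and LMO3 at 1.88 ± 0.0778 and 2.69 ± 0.0424. Mitosis genes showed no detected difference, with a mean of -0.02 (-0.13 to 0.08), nor did FGF and ERK feedback genes, with 0.04 (-0.12 to 0.21). By limma with BH adjustment 0 genes passed, with 1289 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0546.

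TCBPA and TBBPS differ in both halogen and bridge. COL1A1, a fibrillar collagen gene (Entrez gene 1277, chromosome 17, 50184101 to 50201631 in GRCh38), was higher with TCBPA, at 70.1 ± 3.90 FPKM against 48.2 ± 0.127. Mitosis genes were lower and p53 targets and mesenchyme genes higher. COL1A1 differed by 0.53 ± 0.06 with a limma BH-adjusted p of 0.0389, and both TCBPA libraries lay above both TBBPS libraries. The call was lost without TBBPS 1 (adjusted p = 0.156), TBBPS 2 (0.289) or TCBPA 1 (0.214), without the filter on low values (0.15) and in a fit of only the TCBPA and TBBPS libraries, where the smallest adjusted p of any gene was 0.481.

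All 24 mitosis genes were lower with TCBPA than with TBBPS, each with both TCBPA libraries below both TBBPS libraries. Chance puts 16.7% of genes so, and 19.8% of all tested genes lay so. Members of a list are not independent replicates, so their count is not a test against these shares. The median was -0.22 and the mean -0.23 (95% interval -0.33 to -0.12), and 20 passed when adjusted over the list alone (camera, BH-adjusted p = 3.5e-24; 0.443 with an estimated correlation). Intervals of list means are unadjusted. After BH adjustment limma on list means called 0 lists between TCBPA and TBBPS, with a lowest adjusted p of 0.0823. KIF11, a spindle motor gene, was at 26.9 ± 0.969 FPKM and 32.8 ± 0.205. p53 targets had a median of 0.14, 22 of 24 higher, and a mean of 0.15 (0.04 to 0.27; adjusted p = 1.4e-09; 0.443 with an estimated correlation), with BAX, a pro-apoptotic gene, at 119 ± 4.91 and 105 ± 1.36. Without TCBPA 1 the p53 median was 0.08 and without TCBPA 2 it was 0.22. Mesenchyme genes had a median of 0.11, 22 of 23 higher (3.8e-05; 0.443 with an estimated correlation), with COL1A2 at 138 ± 0.870 and 115 ± 11.5, and the median was 0.07 with GC and length trends removed.

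Other lists also differed between TCBPA and TBBPS, with smaller or less stable differences. BMP and TGF-beta targets were higher (0.18, 17 of 19; camera, BH-adjusted p = 7.2e-05; 0.443 with an estimated correlation), with BMP4 at 42.6 ± 3.79 FPKM and 34.2 ± 0.919, a call lost without TCBPA 2. Metallothioneins (0.26, 5 of 6 higher), PPAR targets (0.10), the retinoic acid axis (0.15), the oestrogen axis (0.10), WNT genes (0.05), NOTCH genes (0.06), neural crest (0.14), axon guidance (0.06), ATF4 genes (0.05) and placode genes (0.10) were higher and ribosomal proteins (-0.04) lower, with adjusted p-values from 0.0093 to 0.0485, and 0.443 to 0.778 with an estimated correlation. Each of these 11 calls was lost without 1 of the 4 libraries. MT1F was at 4.62 ± 0.460 and 2.79 ± 0.523, the NOTCH target HES4 at 130 ± 0.516 and 102 ± 2.31, and cyclin D1 gene CCND1 at 77.5 ± 6.01 and 54.3 ± 6.17. No difference was detected in FGF and ERK feedback genes, with a mean of 0.06 (-0.11 to 0.23), or in hedgehog genes, with -0.02 (-0.12 to 0.08).

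**Figure D3:**
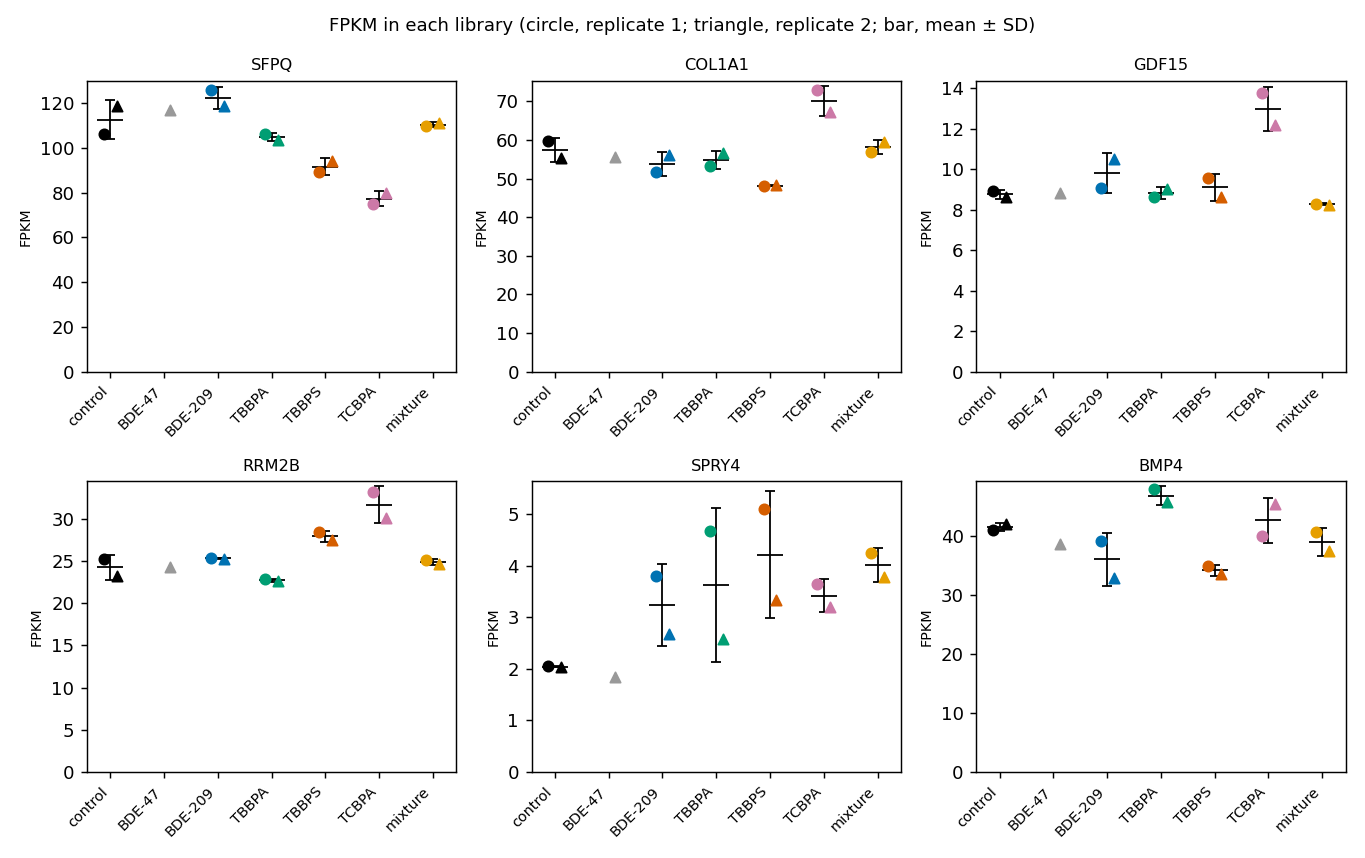
FPKM of SFPQ, COL1A1, GDF15, RRM2B, SPRY4 and BMP4 (vertical axes) in each library by group (horizontal axes), with circles for libraries numbered 1, triangles for those numbered 2 and bars for mean ± SD. SFPQ lies at a mean of 77.3 with TCBPA against 113 in controls, and COL1A1 at 70.1 with TCBPA against 48.2 with TBBPS.

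BDE-209 and BDE-47, the fully and the tetrabrominated diphenyl ether, were compared with 2 libraries against 1, so a difference between the compounds is not separated from the deviation of the BDE-47 library. Neurogenesis genes (0.25, 21 of 24) and placode genes (0.14, 18 of 18) were higher with BDE-209, and ribosomal protein genes (-0.08, 51 of 64 lower) and mitosis genes (-0.07, 22 of 24 lower) were lower. Camera's BH-adjusted p-values were 0.00183, 0.00365, 5.4e-08 and 3.0e-04, and 0.655, 0.601, 0.552 and 0.552 with an estimated correlation. The neuronal tubulin gene TUBB3 was at 58.2 ± 0.375 FPKM with BDE-209 and 49.1 with BDE-47, and the epithelial factor gene GRHL2 at 3.05 ± 0.693 and 1.99. DNA replication (0.06), hypoxia and glycolysis (-0.10) and cholesterol synthesis (-0.06) passed with adjusted p-values of 0.0376, 0.00443 and 0.0168, and 0.608, 0.475 and 0.562 with an estimated correlation. Single genes past limma with BH adjustment numbered 0, with 683 at an unadjusted p under 0.05 and a smallest adjusted p of 0.813. The ribosomal and hypoxia calls were lost with quantile normalization, and the other 5 without 1 BDE-209 library.

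Against the mean of the 5 single compounds, the mixture had lower ribosomal protein, oxidative phosphorylation and mitosis genes and higher FGF and ERK feedback genes. All 64 ribosomal protein genes were lower, with a median of -0.12 (camera, BH-adjusted p = 2.1e-29; 0.443 with an estimated correlation), and 20 passed when adjusted over the list alone. RPS15 differed by -0.31 ± 0.06 and RPL23 by -0.21 ± 0.05. Nuclear oxidative phosphorylation genes had a median of -0.10, 33 of 34 lower (4.2e-15; 0.443 with an estimated correlation), with the cytochrome oxidase gene COX7C at -0.17 ± 0.04. Mitosis genes had a median of -0.11, 23 of 24 lower (7.7e-11; 0.443 with an estimated correlation). Against control, the mitosis median fell no further with the mixture than with TBBPA or TCBPA, at the decimals given above. The mean of the single compounds includes TBBPS and the BDE-47 library, with which mitosis genes were higher than in controls. A mitosis difference of the mixture beyond TBBPA or TCBPA was therefore not shown. FGF and ERK feedback genes had a median of 0.09, 19 of 19 higher (camera, BH-adjusted p = 7.0e-05, and 0.483 with an estimated correlation). Their mean was 0.15 (95% interval 0.02 to 0.28, unadjusted). After BH adjustment limma on list means called 0 lists in this comparison, with a lowest adjusted p of 0.0823. The mean of the single compounds includes the lone BDE-47 library at equal weight. Against control the list median was 0.24 with the mixture and 0.27 with TCBPA, and the list mean 0.31 ± 0.08 and 0.27 ± 0.08. An excess of the mixture over TCBPA was therefore not shown. p53 targets were lower (-0.07, 20 of 24; 2.0e-04; 0.524 with an estimated correlation), with GDF15 at -0.22 ± 0.06. Against control the p53 list was called higher with BDE-47, BDE-209 and TCBPA, which enter the mean, and was not called with the mixture. Neurogenesis genes (0.16), pluripotency genes (0.10) and histones (-0.17) passed at 0.0174, 0.0331 and 0.00257, and 0.738, 0.443 and 0.443 with an estimated correlation. LIN28A, a stem cell RNA-binding protein gene, differed by 0.19 ± 0.05 and HIST1H2AC by -0.60 ± 0.12. By limma with BH adjustment 0 genes passed, with 1201 at an unadjusted p under 0.05 and a smallest adjusted p of 0.131. Across genes, which are not independent replicates, log2 differences in this comparison correlated with transcript length (rho = 0.34), more strongly than in any other comparison. With GC and length trends removed the ribosomal, oxidative phosphorylation and histone medians were -0.07, -0.06 and -0.08. Medians of the other lists after that removal are not given here, so how much of them goes with length stays open. The ribosomal median was -0.03 with quantile normalization and -0.06 without mixture 2, the neurogenesis call was lost without mixture 1, and the pluripotency and histone calls without mixture 2.

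Lists for fatty acid synthesis, mesoderm and endoderm, midbrain and hindbrain, synapse and transmission, and the thyroid hormone axis passed in none of the 11 comparisons with camera, with lowest BH-adjusted p-values of 0.0567, 0.0711, 0.26, 0.227 and 0.0658. KLF9, a thyroid hormone target, was at 0.400 ± 0.0141 FPKM in controls and SOX10, a neural crest factor, at 0.480 ± 0.0424, both below the tested range.

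Fold changes against control were compared across the 12488 genes, which are not independent replicates, for the 15 pairs of treatments. Pearson's r was 0.56 to 0.72 for pairs without BDE-47 and 0.00 to 0.22 for pairs with it. Unchanged groups simulated against the same controls gave 0.50 to 0.51 and 0.41. The covariance exceeded the simulated one by 0.0030 to 0.0101 in pairs without BDE-47 and differed by -0.0061 to -0.0031 in pairs with it. No gene was called in both of any pair, where independent lists give 0.00. That was fixed in advance, since TCBPA alone of the treatments had a called gene. The 2 controls were not divided between the treatments of a pair, which would leave 1 library each, and the simulation gave the controls only the residual spread of each gene, so part of any excess may come from the shared controls.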

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

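Chosen only after the results were seen were the single-library and scaling tests below, quantile normalization and the removal of GC and length trends. Each result here is a difference between compounds that passed camera's BH-adjusted test and had an unadjusted p under 0.05 with an estimated correlation, or a gene past limma's threshold. With an estimated correlation and adjustment over all tests, the adjusted p was 0.443 for each list.

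TBBPS against TBBPA had median log2 differences of -0.29 for BMP and TGF-beta targets, -0.12 for mesenchyme and extracellular matrix, 0.21 for mitosis, 0.05 for NRF2 targets, -0.11 for the oestrogen axis and -0.14 for WNT genes. These medians are before removal of GC and length trends, and differences between TBBPS and TBBPA correlated with GC content across genes (rho = -0.38). TCBPA against TBBPA had 0.06 for ER chaperones, 0.06 for NRF2 targets and 0.18 for p53 targets. TCBPA against TBBPS had 0.18 for BMP and TGF-beta targets, 0.11 for mesenchyme, 0.26 for metallothioneins, -0.22 for mitosis, 0.10 for the oestrogen axis, 0.14 for p53 targets, 0.10 for PPAR targets and 0.15 for the retinoic acid axis. COL1A1 differed by 0.53 between TCBPA and TBBPS. The mixture differed from the mean of the single compounds by -0.12 for ribosomal proteins, -0.11 for mitosis, -0.10 for oxidative phosphorylation, 0.10 for pluripotency genes and -0.17 for histones. These medians too are before removal of GC and length trends, and differences in this comparison correlated with transcript length across genes (rho = 0.34).

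Mitosis genes were lower with TCBPA than with TBBPS, by -0.22. A bias with GC content or length as the whole cause is argued against, since the median was -0.21 after both trends were removed (mean -0.22 ± 0.05, from -0.23 ± 0.05). One library alone as the cause is argued against too, since the median nearest 0 with 1 library left out was -0.17. A difference in proliferation tied to the compounds stays open as a hypothesis, and so may a difference in density or harvest between dishes, which the labels do not let be tested.

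Ribosomal protein genes were lower in the mixture than in the mean of the single compounds, by -0.12. After removal of GC and length trends the median was -0.07 (mean -0.08 ± 0.03, from -0.13 ± 0.04), which lies between what that bias and its absence predicted, so the part it plays cannot be told apart from the rest. Without mixture 2 the median was -0.06, and with quantile normalization it was -0.03, in line with a large share coming from that library or from the scaling of the values. A response to the mixture itself may add to it and was not tested separately.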

How the results depend on the processing

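Quantile normalization, removal of GC and length trends, limma on list means and leaving out the 5 treated libraries numbered 1 were chosen after the data were seen. Counts of genes past the threshold moved as follows, and where nothing else is said the cause was not tested. Without the filter on low values 1 gene passed with BDE-47, 0 with TCBPA, 0 between TCBPA and TBBPS and 1 between BDE-209 and BDE-47. In fits of only the groups compared, 158 passed with TCBPA, 1 with the mixture, 1 between TBBPS and TBBPA, 0 between TCBPA and TBBPS, 1 between BDE-209 and BDE-47 and 1 between the mixture and the mean of the single compounds. At an adjusted p of 0.01, by construction stricter, 0 passed with TCBPA and 0 between TCBPA and TBBPS. With quantile normalization 0 passed with TCBPA and 2 between TCBPA and TBBPA. With GC and length trends removed 8 passed with TCBPA and 0 between TCBPA and TBBPS, where COL1A1 was not tested because it had no GC or length value. With the 5 treated libraries numbered 1 left out 3 passed with TCBPA, SFPQ not among them, and 2 with the mixture. With 1 library left out at a time the counts ranged from 0 to 1 with TBBPA, TCBPA, the mixture, between TBBPS and TBBPA and between the mixture and the mean, from 0 to 4 between TCBPA and TBBPS, and stayed at 0 in the others.

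With the replicate number as a block, 3 genes passed with BDE-209, 1 with TBBPA, 273 with TBBPS, 452 with TCBPA, 115 with the mixture, 1 between TBBPS and TBBPA, 4 between TCBPA and TBBPA, 16 between TCBPA and TBBPS and 3 between the mixture and the mean. Deviations of libraries with the same number correlated by -0.03 to 0.48 across genes, above 0.1 in 13 of the 15 pairs of groups, and in each of the 6 groups with 2 libraries the one numbered 1 lay higher on the first principal component. That is a hint from the data that libraries with the same number share something, and the labels do not say that a number marks a shared culture, batch or day.

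List calls numbered 115 in the planned test, 0 with an estimated correlation, 0 by fry and 0 by limma on list means. The block called 128 and kept 112 of the 115, quantile normalization called 109 and kept 99, GC and length removal called 107 and kept 100, and leaving out 1 library gave 103 to 124, BDE-47 aside. Without the BDE-47 library its comparisons drop out, and 100 lists were called, with 95 of the 95 calls that still had a value kept. The median correlation of fold changes between treatments ranged from 0.38 to 0.70 with 1 library left out, against 0.60. Direction turned for ATF4 genes with BDE-209 without BDE-209 2 (0.00, against 0.24 without BDE-209 1), for RPS3 with TBBPA under quantile normalization (-0.02), for HIST1H2BD with TBBPS without TBBPS 2 (-0.03, against 0.45 without TBBPS 1) and for SLC30A1 between TCBPA and TBBPS without TCBPA 1 (-0.15, against 0.46 without TCBPA 2). Alternatives that need counts (other count normalizations, count tests and count filters) were not run, since the values are FPKM, and depth is not known.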

Other observations

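The control position test and the contrast of all treated libraries were chosen after the results were seen, as were quantile normalization and the removal of GC and length trends. The first principal component carried genes that pattern the early brain. At the end where the treated libraries numbered 1 lay were the WNT receptor genes FZD8 and FZD5, the placode and forebrain gene DLX5 and the thyroid deiodinase DIO3. At the end of the controls and BDE-47 were BARHL1, WNT8B, WLS, NR2E1, RFX4 and the releasing hormone gene TRH. WNT8B was at 90.59 and 105.67 FPKM in the controls, 99.16 with BDE-47, 10.29 and 57.62 with TBBPS and 24.08 and 63.76 with TCBPA. BARHL1 was at 41.42 and 39.15 in the controls and 1.34 and 19.30 with TBBPS. Of 4533 gene ontology terms ranked on the component by camera with a preset correlation, 37 had a BH-adjusted p under 0.05. Wnt-activated receptor activity (6.1e-07) and inner ear morphogenesis (8.3e-05) lay at the high end, and midbrain development (8.3e-05) and negative regulation of smoothened signaling (1.9e-04) at the low end. Genes are not independent replicates, and the component was found in these same libraries.

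All 11 treated libraries were set against the 2 controls. With the replicate number as a term, limma called 1 gene with BH adjustment: CRABP2, a retinoic acid binding protein gene, at 0.38 ± 0.05 (adjusted p = 0.0324), with 11 of 11 treated libraries above both controls. Without that term 0 genes passed, with 821 at an unadjusted p under 0.05 and a smallest adjusted p of 0.436. Genes near the threshold that did not pass were BMP2 at -0.35 ± 0.06 (adjusted p = 0.066), lower in 11 of 11, and ELAVL2, MECOM and BEX1, each at 0.0671. Choosing any library numbered 1 and any numbered 2 as controls gave at least as many genes in 3 of the 42 choices, counting the real one. The real choice gave 1 gene and the highest other, control 1 with BDE-47, gave 28, while TCBPA 1 with TCBPA 2 gave 15. Both are several times the real count, which points to a structure of the libraries whose source was not tested. The first holds a control beside BDE-47 and the second is the whole TCBPA group, and an effect of TCBPA would give such genes too. These choices are therefore a weak test of chance and cannot exclude it.

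FGF and ERK feedback genes rose in 5 of the treated groups (BDE-209, TBBPA, TBBPS, TCBPA and the mixture), with adjusted p-values of 0.443 to 0.654 with an estimated correlation, and the mean over those groups of the list's median was 0.18. The BDE-209 call was lost without BDE-209 1 or either control, and the TBBPA median was 0.08 without TBBPA 1. Removing GC and length trends left the mean over groups at 0.17 and quantile normalization at 0.18, which argues against either as the whole cause. As large a distance of the chosen controls from the rest came from 2 of the 42 choices, the real one at 0.2005 and control 1 with BDE-47 at 0.2103, but the list was picked because it stood apart from the controls, so this does not test chance, and a chance position of the controls stays open. A difference in differentiation state or culture between libraries, seen along the first component, may account for part of it and was not tested, and a response to the compounds stays open as a hypothesis.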
